A study of Mus musculus with 2 samples.

How the data were processed

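Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for H3K27me3, the trimethylated lysine on histone H3 that Polycomb repressive complex 2 deposits at silent genes. The tissue was whole liver of mouse embryos at day 14.5, and both samples form 1 group of 2 biological replicates. Per the labels, each replicate was a separate tissue sample that pooled male and female embryos of the same strain. The labels give no second condition, so replicate was compared with replicate, and marked genes and regions with the rest of the genome.

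The peak lists were used as the authors deposited them, in narrowPeak format on the mouse build mm10. There were 4 lists: one for each replicate, one called on the alignments of both replicates together (the pooled list), and one of replicated peaks derived from the other lists. Per the deposited text notes, replicate 1's list and the pooled list were made from alignments and the same 2 further files of unnamed kind, and replicate 2's list from alignments and 1 of these files. The aligner, the peak caller, its threshold and the rule that makes a peak replicated are not given in the sources used here. In the deposited lists each peak carries a display score, a signal value whose scale is not stated, and −log10 p and −log10 q values. The authors' −log10 p and −log10 q ranked and filtered peaks within a list, with the signal value used only to order peaks of equal p, and the score was not used. Every deposited value belongs to a single peak and was not compared between lists. No read counts were used, so the depth of each replicate is unknown and no interval or detection limit based on reads could be given.

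Gene positions came from GENCODE release M21 and sequence from GRCm38, the same build as mm10. The analysis covered 21938 protein-coding genes on chromosomes 1 to 19, X and Y, and 1 peak of replicate 2 on another sequence was left out. The start site of a gene was the 5' end of its gene record. A gene was called marked when a peak of the replicated list overlapped the 2 kb window centred on that site. As a measure of extent, the length covered by peaks within 5 kb on either side of the start site was computed for each gene, out of 10 kb. Coverage named for a gene refers to this 10 kb alone. A gene without covered sequence may thus have peaks elsewhere, for example at another transcript start. Domains were made by joining peaks separated by 3 kb or less. Observed over expected CpG and GC content were computed for each start window, and windows with a ratio of 0.6 or more and GC of 50% or more were called CpG-rich.

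The replicates' lists were compared by the share of peaks with an overlap of 1 bp or more, against 100 shuffles of the other list within its chromosomes, outside assembly gaps of 1000 bp or more. The location of peaks was compared with 100 shuffles in the same way. With 100 shuffles the smallest permutation p is 0.0099. Each of 17 gene lists, and each of 21 chromosomes, was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists or the chromosomes. Mean CpG ratios were compared by a two-sided permutation test with 100000 resamples. Intervals of shares are exact Clopper-Pearson 95% intervals. Where no gene was marked, the upper limit printed is instead 3 counts of the total, which is lower than the upper end of the two-sided exact interval. Intervals and limits cover counting error over genes only. These p-values treat genes as independent, although neighbouring genes can lie in 1 domain. The p-values of the 2 replicates' lists are not combined, and each list was tested alone as an alternative.

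The comparisons, the gene lists, the tests and most alternatives were fixed before the data were examined. The genes named were chosen by a rule fixed at the same time. In each list with marked members it takes the 3 marked members with the longest covered length and up to 2 unmarked members, first in list order. In the hepatoblast, postnatal liver, erythroid and housekeeping lists it takes up to 6 marked members. It also takes the genes in the 10 longest domains and each Hox cluster. Of 688 genes written in the lists by symbol, 4 were not found under that symbol. Alternatives were a −log10 q of 2 or more, equal numbers of best peaks, joined peaks, larger overlaps, windows of 0.5 kb and 2.5 kb on either side, 50% of the window covered, any transcript start, CpG-rich windows alone, the pooled list, and each replicate's list alone. Further alternatives, chosen after seeing the data, were replicated peaks found in both replicates' lists, leaving out X and Y, and the share of peaks on X under the other thresholds.

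Overlaps were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and pyfaidx 0.9.0.4, tests with SciPy 1.17.1, and plots with matplotlib 3.10.9. The overlap step was tested on simulated data over the same 21938 genes and found 200 of 200 planted genes, and it gave the same 751 windows as bedtools 2.31.1. In 500 simulated lists of 45 genes, 2.4% were called at a true marked share of 19%. At a share of 40%, 87% were called, and at a share of 60%, 100%. The simulation marked genes independently and called each list on its unadjusted p. These rates are therefore not the false-call rate or power of the adjusted test, or of lists whose genes share domains.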

Results

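H3K27me3 was mapped in mouse embryonic liver at day 14.5, when the organ holds hepatoblasts, the precursors of hepatocytes and bile duct cells, together with a large population of developing blood cells. The data were peak lists for 2 biological replicates of 1 group, a list called on both replicates pooled, and a list of replicated peaks. Replicate 1's list held 25941 peaks covering 19.2 Mb and replicate 2's held 18459 peaks covering 15.9 Mb. The pooled list held 22118 peaks over 21.4 Mb. The replicated list held 15611 peaks over 19.7 Mb, or 0.724% of the genome, with a median width of 582 bp and a longest peak of 20975 bp. Read depth is unknown, so the difference in peak number cannot be set against sequencing depth.

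The first comparison asked whether the replicates marked the same places. Of replicate 2's peaks, 82.0% (15128) overlapped a peak of replicate 1, and of replicate 1's peaks, 55.3% (14349) overlapped a peak of replicate 2. Shuffled lists gave means of 1.77% and 1.25%, and the observed shares exceeded all 100 shuffles (permutation p = 0.0099, the smallest possible). Sharing was more frequent among strong peaks. Among the top 25% of each list by −log10 p, 96.3% of replicate 1's and 99.8% of replicate 2's peaks were shared, against 30.4% and 63.5% in the lowest 25%. Replicate 1's list was 1.41 times as long, but its covered length was 1.20 times that of replicate 2. At a −log10 q of 2 or more, 15133 and 9693 peaks were left, and joining peaks across 3 kb or less left 9219 and 6375 regions. With a reciprocal overlap of 50%, the shared shares fell to 31.3% of replicate 1's and 44.0% of replicate 2's peaks.

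Each replicated peak was identical to a peak of the pooled list. Of these peaks, 10523 (67.4%) overlapped both replicates' own lists, 3127 (20.0%) overlapped replicate 1's alone, 1218 (7.80%) replicate 2's alone, and 743 (4.76%) neither. By the replicated list, 4220 of 21938 protein-coding genes (19.2%) had a peak within 1 kb of the start site. Replicate 1's own list marked 4418 genes (20.1%) and replicate 2's marked 4031 (18.4%). Of the genes marked in replicate 2's list, 96.0% were also marked in replicate 1's, and 87.6% in the other direction.

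The mark was widespread on the lists of developmental regulators. These lists are named for tissues other than liver, but their members were not chosen for lacking a role in liver. All 39 Hox genes, the factors that set position along the body axis, were marked (95% interval 91.0% to 100%, adjusted p = 5.92e-28, Fisher's exact test against all other genes). They lay in only 6 joined domains, so this interval and p overstate the number of independent observations. Of the transcription factors of the neural lineage, 70 of 71 were marked (98.6%, adjusted exact p = 2.38e-48). Peaks covered the full 10 kb around the starts of Pax2, a kidney and midbrain factor, Olig2, an oligodendrocyte and motor neuron factor, and Lmx1b. Neurod6 was the unmarked member, with 0.449 kb covered near its start (0.475 kb in replicate 1's list and 0.227 kb in replicate 2's). Of the heart, muscle and mesenchyme factors, 43 of 50 were marked (86%, adjusted exact p = 1.11e-23). Gata6 and Pax9 were covered over the full 10 kb and the kidney progenitor factor Six2 over 9.97 kb, whereas Myf5 and Myf6, neighbouring muscle factors, had no covered sequence. Of the pancreas and gut factors, 18 of 20 were marked (90%, adjusted exact p = 3.90e-11), with Barx1 at 9.97 kb, Nkx2-3 at 9.90 kb and Insm1 at 9.63 kb. Isx, an intestinal factor, and Pax4, an endocrine pancreas factor, were unmarked.

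Secreted ligands of the Wnt, Bmp, Fgf and Hedgehog families and their antagonists were marked at 45 of 50 genes (90%, adjusted p = 1.62e-26, Fisher's exact test). Covered length was 8.78 kb at Wnt10b, 8.63 kb at Fgf8 and 7.80 kb at Wnt3a, and Wnt8b and Fgf4 had none in the replicated list, although replicate 2's own list had 0.542 kb at Fgf4. When any transcript start was counted, 49 of 50 ligands (98%) were marked. Most ligands unmarked at the start of the gene record thus had a peak at another annotated start. Genes that work in mature neurons were marked at 32 of 48 (66.7%, adjusted exact p = 2.71e-12). Among them, the GABA-synthesising enzyme gene Gad2 had 8.62 kb covered, the vesicular GABA transporter gene Slc32a1 8.20 kb, and the vesicular glutamate transporter gene Slc17a7 6.45 kb. Gad1, which encodes the related GABA-synthesising enzyme, had none and was unmarked, as was the synaptic vesicle gene Syp with 0.408 kb (0.641 kb in replicate 1's list and 0 kb in replicate 2's). These values are for the start of the gene record, and values at other transcript starts are not given here. With any transcript start counted, 36 of 48 neuronal genes (75%) were marked, so the unmarked call can depend on the start used. The calls on these 6 developmental and neuronal lists were the same with each replicate's list alone.

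**Figure D1:**
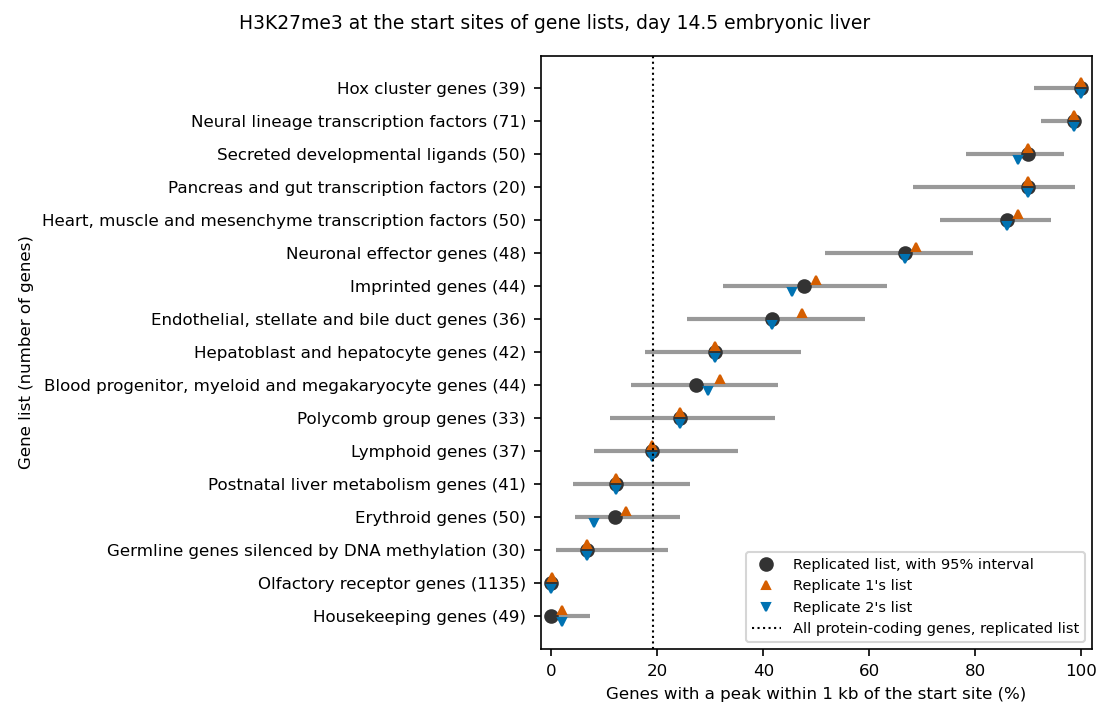
Percentage of genes in each list with an H3K27me3 peak within 1 kb of the start site (x axis), with the list and its number of genes on the y axis. Circles are the replicated list with exact 95% intervals as bars, triangles are each replicate's own list, and the dotted line is the 19.2% of all protein-coding genes; the Hox list lies at 100% and the housekeeping list at 0%.

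The longest domains lay over the Hox clusters. After joining peaks, the 6558 domains had a median length of 2.38 kb, and 371 were 10 kb or longer, of which 306 (82.5%) held the start of a protein-coding gene. The longest, 136 kb on chromosome 15 from 102907048 to 103043537 (mm10), held the 9 genes Hoxc4 to Hoxc13. Domains of 128 kb on chromosome 6 from 52149839 to 52277902, 119 kb on chromosome 2 from 74646402 to 74764995, and 107 kb on chromosome 11 from 96249626 to 96356680 held the Hoxa cluster, the Hoxd cluster with the adjacent homeobox gene Evx2, and Hoxb2 to Hoxb9. The Hoxa and Hoxd domains also held the annotated genes 5730596B20Rik, Gm28308 and Gm28230. Peaks covered 94.2% of the span from the first to the last gene of Hoxc, 93.0% of Hoxa, 88.9% of Hoxd and 65.7% of Hoxb, where Hoxb13 lay in a separate domain of 40.6 kb. In replicate 1's list these shares were 89.4%, 89.0%, 85.9% and 61.9%, and in replicate 2's 87.7%, 86.6%, 81.1% and 57.2%.

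The other domains among the 10 longest each held factors of early patterning. They were 60.1 kb over Zic1 and Zic4, cerebellar factors, on chromosome 9, 50.2 kb over Nr2f1 and 45.3 kb over the neural crest factor Tfap2a on chromosome 13, 43.4 kb over the heart and limb factor Hand2 on chromosome 8, and 39.5 kb over the forebrain factor Lhx2 on chromosome 2. Replicate 1's list gave 447 domains of 10 kb or longer and replicate 2's gave 324. Joining across 10 kb instead of 3 kb gave 667.

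**Figure D2:**
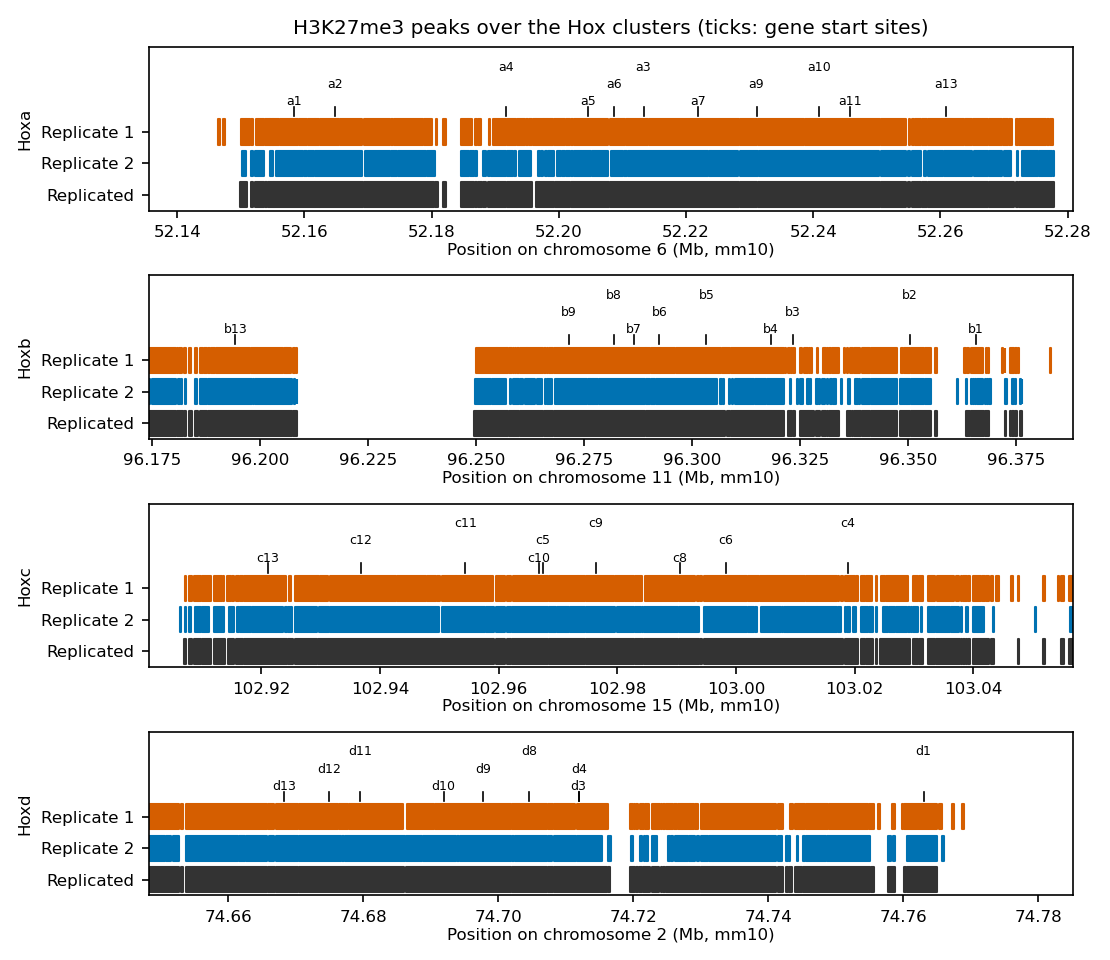
H3K27me3 peaks of replicate 1, replicate 2 and the replicated list as filled blocks along the 4 Hox clusters, with position in Mb (mm10) on the x axis and gene start sites as ticks. Blocks of the replicated list cover 94.2% of the Hoxc span and 65.7% of the Hoxb span, where Hoxb13 is set apart from the rest.

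The next lists were those of the liver's own cells. Of the hepatoblast and hepatocyte list, 13 of 42 genes were marked (31.0%, 95% interval 17.6% to 47.1%), which did not pass the test against other genes (adjusted p = 0.115, Fisher's exact test). The widest coverage lay over liver transcription factors. Foxa1 (start at 57546916 on chromosome 12) had 9.93 kb of 10 kb covered, Onecut2 9.86 kb, Onecut1 8.95 kb, Foxa2 7.09 kb, Prox1 6.79 kb and Cebpa 4.64 kb. In the replicates' own lists Foxa1 had 9.94 kb and 9.37 kb, and Cebpa 4.57 kb and 4.58 kb. No sequence within 5 kb of the starts of Alb and Afp, the albumin and alpha-fetoprotein genes, was covered. Limited to CpG-rich start windows, all 11 remaining members were marked, against 31.2% of other such genes (adjusted p = 7.54e-06, Fisher's exact test), and with 50% of the window covered the list also passed the test at 28.6% against 13.6% (adjusted p = 0.0167).

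Genes of postnatal liver metabolism, most of which rise around and after birth, were marked at 5 of 41 (12.2%, adjusted p = 0.366, Fisher's exact test). The share was 7.32% at a −log10 q of 2 or more and with 50% of the window covered, 19.5% when any transcript start was counted, and 1 of 2 genes among CpG-rich windows, and it passed the test under none of these settings. Igfbp2, which encodes a binding protein of insulin-like growth factors, had 4.88 kb covered, Fbp1 of gluconeogenesis 1502 bp, and the sterol hydroxylase gene Cyp27a1 1.35 kb. Gnmt and Abcg8 had 0.307 kb and 0.268 kb, with best −log10 q values of 1.29 and 0.712. In replicate 1's and replicate 2's own lists they were 3.93 kb and 2.69 kb at Igfbp2, 1.67 kb and 0.267 kb at Fbp1, 0.412 kb and 0.557 kb at Cyp27a1, and 0.665 kb and 0.255 kb at Gnmt. Abcg8 had 0.296 kb in replicate 1's list and was not marked in replicate 2's. Cyp2e1 and Cyp3a11, drug-metabolising enzymes of the adult liver, had no covered sequence.

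Erythroid genes were marked at 6 of 50 (12%, 95% interval 4.53% to 24.3%, adjusted p = 0.339, Fisher's exact test), with 7 marked in replicate 1's list and 4 in replicate 2's. With 50% of the window covered 3 of 50 (6%) were marked, and among CpG-rich windows 3 of 14 (21.4%), without passing the test under either setting. Coverage reached 7.16 kb at Ank1, 5.52 kb at Dmtn and 5.11 kb at Add2, which encode proteins of the red cell membrane skeleton. Hba-x, the embryonic zeta globin gene, had 1.72 kb, Tmod1 0.752 kb and Ldb1 0.751 kb. Hba-x, with a best −log10 q of 1.29, and Tmod1 were not marked in replicate 2's own list. In replicate 1's and replicate 2's own lists, Hba-x had 0.824 kb and 1.18 kb covered, Tmod1 0.227 kb and 0 kb, and Ldb1 0.240 kb and 0.408 kb. Gata1 and Klf1, the erythroid master regulators, had no covered sequence in either replicate's list. Neither start window was CpG-rich (observed over expected ratios of 0.228 and 0.266), and only 14.1% of all genes without a CpG-rich window were marked. At Ank1, 13 of the 16 annotated transcript starts had no peak within 1 kb.

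Genes of blood progenitors, myeloid cells and megakaryocytes were marked at 12 of 44 (27.3%, adjusted p = 0.236, Fisher's exact test). The macrophage factor Mafb was covered over the full 10 kb, the progenitor factor Gata2 over 9.20 kb and the platelet receptor gene Gp1bb over 8.49 kb. At the progenitor factors Runx1 and Myb, no sequence within 5 kb of the start of the gene record was covered, and their other transcript starts were not examined singly. Lymphoid genes were marked at 7 of 37 (18.9%, adjusted exact p = 1). Pax5, the B cell factor, had 9.52 kb covered, Lef1 9.29 kb and Gata3 9.24 kb, and the T cell receptor subunit gene Cd3e had none. Among CpG-rich start windows 7 of 10 blood progenitor and myeloid genes (adjusted p = 0.0199) and 4 of 5 lymphoid genes (adjusted p = 0.0482, Fisher's exact test) were marked, against 31.3% of other such genes in both cases.

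Genes of endothelial, stellate and bile duct cells were marked more often than other genes, at 15 of 36 (41.7%, adjusted p = 0.00353, Fisher's exact test), and at 8 of 9 among CpG-rich windows. The mesenchymal receptor gene Pdgfra had 9.24 kb covered, the stellate cell gene Reln 6.49 kb and Ngfr 6.41 kb. Pecam1 and Cdh5, adhesion genes of endothelium, had no covered sequence. Genes of the Polycomb complexes themselves were marked at 8 of 33 (24.2%, adjusted exact p = 0.537). Cbx8 (9.21 kb), Cbx4 (6.04 kb) and Bmi1 (5.96 kb) encode parts of Polycomb repressive complex 1. Ezh2, the main methyltransferase for this mark, was unmarked with no covered sequence in the replicated list, and Ezh1 was unmarked with 2.10 kb nearby (2.19 kb in replicate 1's list and 1.13 kb in replicate 2's).

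Imprinted genes were marked at 21 of 44 (47.7%, adjusted p = 3.75e-05, Fisher's exact test). Grb10 had 8.13 kb covered, Sfmbt2 7.29 kb and Dio3 7.11 kb. Igf2 had 3.97 kb within 5 kb of its start but no peak in its start window, and Igf2r had none. The files do not separate the parental alleles. Housekeeping genes were marked at 0 of 49, which allows a share of up to 6.12% (adjusted exact p = 1.23e-04). Each replicate's own list marked 1 housekeeping gene, a different one in each, and the pooled list marked 2. Olfactory receptor genes, silent in most tissues outside the nose, were marked at 0 of 1135, which allows up to 0.264% (adjusted exact p = 9.63e-108), and replicate 1's own list marked 2 and the pooled list 1. None of them had a CpG-rich start window, so this list could not be compared among such windows.

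Germline genes that DNA methylation silences in somatic cells were marked at 2 of 30 (6.67%, adjusted p = 0.145, Fisher's exact test), and at 1 of 5 among CpG-rich windows. The marked members were Tex15 with 0.820 kb covered and Tdrd1 with 0.528 kb (0.267 kb in replicate 1's list and 0.686 kb in replicate 2's). The germ cell genes Dazl and Ddx4 had no covered sequence. With the window narrowed to 0.5 kb on either side the share was 3.33% (adjusted exact p = 0.0490), and with 50% of the window covered it was 0% (adjusted exact p = 0.0396), so under both settings the list passed the test as less often marked.

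Peaks were enriched at promoters and exons. Promoters, taken as 1 kb on either side of a start site, held 29.0% of peak length against 1.72% after shuffling, a 16.8-fold excess. Other exons held 11.6% against 3.61%. Introns held 31.0% against 37.3% and intergenic sequence 28.5% against 57.3%, both lower than after shuffling (permutation p = 0.0099 for each of the 4 locations, the smallest possible). With promoters of 2.5 kb on either side, the shares were 53.1% in promoters, 7.30% in other exons and 18.6% in introns. Marked start windows were richer in CpG. Their observed over expected CpG ratio was 0.593 ± 0.170 (SD, 4220 genes) against 0.418 ± 0.256 (SD, 17718 genes) in unmarked ones, a difference of 0.175 (permutation p = 1e-05, the smallest possible). Of genes with CpG-rich windows, 31.4% were marked (2048 of 6532), against 14.1% of the rest (2172 of 15406). Among the genes named above as unmarked, Alb, Afp, Gata1, Klf1, Cd3e, Pecam1 and Cdh5 had windows that were not CpG-rich, whereas those of Myb, Ezh2, Actb and Dazl were.

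Marked genes were unevenly spread over chromosomes. The X chromosome had 89 of 948 genes marked (9.39%, adjusted p = 2.87e-16, Fisher's exact test). Replicate 1's own list marked 126 X genes (13.3%) and replicate 2's marked 80 (8.44%). With 50% of the window covered the X share was 5.27%, under a rule that marked 3000 genes overall in place of 4220. None of the 4 lists held a peak anywhere on the Y chromosome, so its 183 genes do not show whether the mark could be detected there. Chromosome 7 was also low at 15.0% (adjusted exact p = 1.27e-06), as were 17 at 16.0% (0.0201) and 14 at 16.3% (0.0466). These shares count all protein-coding genes, including the olfactory receptor genes, none of which was marked. The position of such families was not taken into account. Chromosomes 12 (26.6%, adjusted exact p = 1.51e-05) and 15 (26.2%, adjusted exact p = 6.20e-06) were highest, followed by 18 (23.8%), 4 (22.1%) and 11 (21.7%), which also passed the test. The calls on chromosomes 14 and 18 were lost with replicate 1's list alone (adjusted exact p = 0.0792 and 0.0697), and those on 11 and 14 with the window of 0.5 kb (0.113 and 0.119) or with 50% of the window covered (0.219 and 0.176). That on 14 was also lost at a −log10 q of 2 or more (0.0811).

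The replicates differed most on the X chromosome. Replicate 1's list held 1510 peaks there (5.82% of its peaks, 95% interval 5.54% to 6.11%) and replicate 2's held 297 (1.61%, 1.43% to 1.80%), a ratio of 5.08, against 1.35 on the autosomes. The odds ratio of the X share was 3.78 (p = 3.29e-121, Fisher's exact test over peaks, which are not independent). It was 2.55 with the same number of best peaks in both lists, 2.74 at a −log10 q of 2 or more and 6.29 with peaks joined across 3 kb or less. Replicate 1's X peaks were narrow, with a median of 235 bp against 337 bp on its autosomes, and 14.8% of them touched a promoter, against 45.8% of replicate 2's X peaks. The X ratio was above the autosomal median of 1.34 in each of the 17 bins of 10 Mb that held peaks, and ranged from 1.43 to 16.3 where replicate 2 had any. The highest count was 336 against 27 peaks between 100 and 110 Mb.

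**Figure D3:**
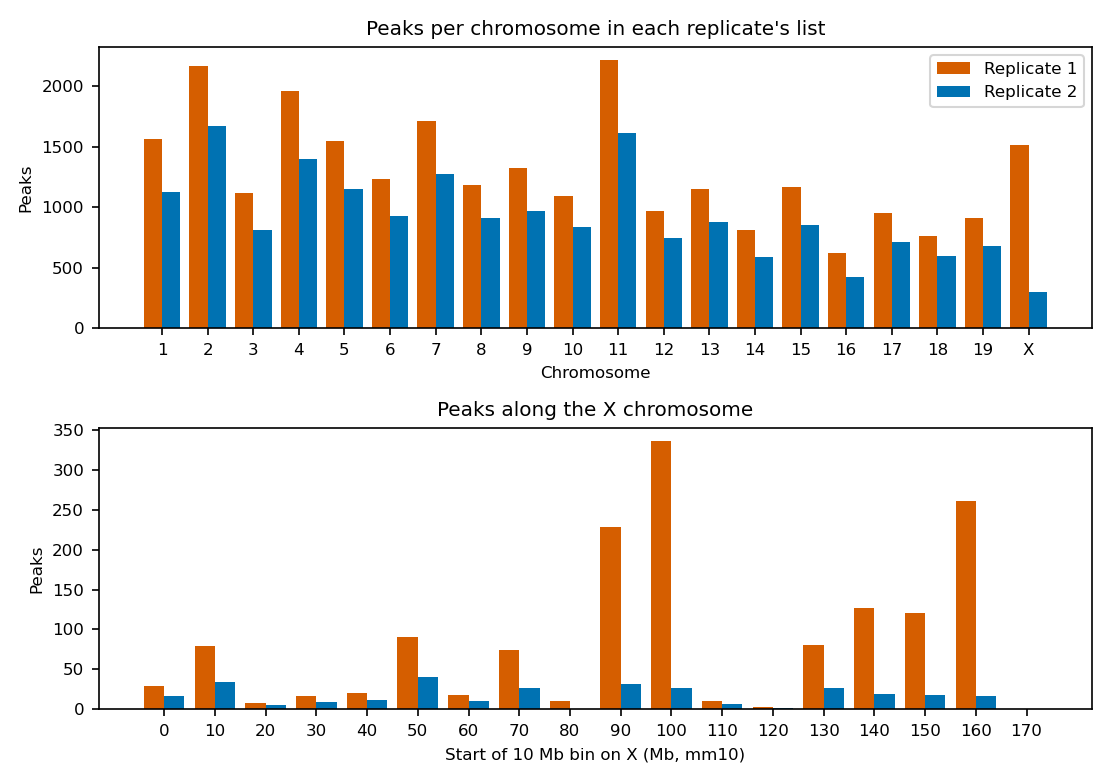
Number of peaks (y axis) per chromosome (top) and per 10 Mb bin of the X chromosome (bottom, bin start in Mb, mm10) in replicate 1's and replicate 2's own lists. On X the lists hold 1510 and 297 peaks, with the tallest bin at 336 against 27 from 100 Mb.

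Genes marked in 1 replicate's list only numbered 549 for replicate 1 and 162 for replicate 2, beside 3869 marked in both. Of replicate 1's 549, 8.93% were on X, against 1.99% of the 3869 (p = 1.60e-14, Fisher's exact test). Among the 17 gene lists, only the neural transcription factors passed the test, with 0 of 549 against 70 of 3869 genes (adjusted exact p = 0.00524). Each replicate's list marked 70 of the 71 members, so almost none could be marked in 1 list only. The result therefore does not show that the replicates differ in kind of gene. No list differed for the 162 genes of replicate 2. With 50% of the window covered, 438 genes in place of 711 were marked in 1 replicate's list only.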

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

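Among the alternatives below, leaving out X and Y, keeping replicated peaks found in both replicates' lists, and the X share under other thresholds were chosen after seeing the data. Of 325 values recomputed under an alternative, 306 kept their side of the threshold or stayed within 1.5 times the main count, 7 lost their call, 5 gained one in the main direction, 6 counts moved, and 1 list level with other genes gained a call above them. Of the 306, 9 values in 3 lists without a call under either setting changed direction, 7 of them for the lymphoid list and 1 each, with CpG-rich windows, for the postnatal liver and Polycomb lists. At a −log10 q of 2 or more the replicates' lists held 15133 and 9693 peaks, and joined at 3 kb 9219 and 6375 regions. The share of peaks found in the other list passed the shuffles under each overlap rule run, from 31.3% to 65.9% for replicate 1 and from 44.0% to 88.1% for replicate 2. With CpG-rich start windows alone, the hepatoblast list (100%) and the blood progenitor list (70%) passed the test, and the lymphoid list, level with other genes at 18.9% in the main result, passed it at 80%, on 5 genes. The odds ratio of the X share was 2.74 at a −log10 q of 2 or more, 2.55 with equal numbers of best peaks and 6.29 with joined peaks. With 50% of the window covered, the hepatoblast list (28.6%) and the germline list (0%) passed, as did the germline list with 0.5 kb on either side (3.33%), and 438 genes were marked in 1 replicate only. Joining at 10 kb gave 667 domains of 10 kb or longer. The cause of these changes was not tested, beyond the smaller number of genes in CpG-rich windows. The 7 lost calls were those on chromosomes 11, 14 and 18. With 1 replicate left out, marked genes numbered 4031 or 4418 and long domains 324 or 447. Over all settings, marked genes ranged from 3000 with 50% of the window covered to 4665 with any transcript start. Replicated peaks found in both replicates' lists marked 3831 genes. Depth is unknown, so peaks missed for lack of reads cannot be told from places without the mark. No paired analysis was possible because the design has 1 group.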

Other observations

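The gene families, the long noncoding RNA count, the tests of the X excess and the comparison of hepatic with erythroid factors were chosen after the results were seen, and the test of transcript starts in erythroid genes was fixed before its result. In 28 gene families taken by symbol, shares differed widely. Ephrins and Eph receptors were marked at 20 of 22 genes (adjusted p over the families = 6.69e-12, Fisher's exact test), semaphorins at 14 of 20, and Slit, Robo and netrin genes at 11 of 15. Potassium channel genes were marked at 64 of 93 (adjusted exact p = 3.68e-24), glutamate receptors at 21 of 27, calcium channels at 17 of 26 and GABA-A receptors at 8 of 19 (adjusted p = 0.0226), whereas sodium channels, at 3 of 10, did not pass the test (adjusted exact p = 0.449). Among regulators, LIM homeobox factors were marked at 12 of 12, Iroquois factors at 6 of 6, Sox factors at 17 of 19 and forkhead factors at 29 of 44. Collagens, the fibrous matrix proteins, were marked at 24 of 45 (adjusted exact p = 9.60e-07).

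Other large families were marked less often than the rest. Zinc finger genes with Zfp symbols were marked at 37 of 394 (9.39%, adjusted p = 3.36e-07, Fisher's exact test), vomeronasal receptors at 0 of 329, which allows up to 0.912%, replication-dependent histone genes at 1 of 67, ribosomal protein genes at 1 of 79 (2 in each replicate's own list) and cytochromes P450 at 10 of 100 (adjusted p = 0.0199). Clustered protocadherins, at 10 of 55, did not pass the test (adjusted exact p = 1). Of 5854 long intergenic noncoding RNA genes, 343 were marked (5.86%, 95% interval 5.27% to 6.49%), and of the 5226 whose start lay over 5 kb from any protein-coding start, 183 (3.50%) were.

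The excess of X peaks in replicate 1 was uneven, with 71.1% of its 1510 X peaks in the 5 bins of 10 Mb that held most, where it had 1073 peaks against 111. A longer or looser list as the only cause is argued against by the odds ratio of 2.55 at the same number of best peaks. That cut lowered the odds ratio from 3.78 and replicate 1's X peaks from 1510 to 738, so its weaker peaks held part of the excess. The further parent file of replicate 1's list is not argued against. The pooled list shares that file and had 1.94% of its peaks on X, but it also holds replicate 2's alignments. A local event on X as the only cause is argued against by a ratio above the autosomal median in 17 of 17 bins. That median is a low bar, and 13 bins lay above the autosomal 95th percentile of 1.79. The highest autosomal bin reached 2.5, and some X bins held few peaks, such as 8 against 5 from 20 to 30 Mb. Outside the 5 fullest bins the X ratio was still 2.35, with 437 against 186 peaks (p = 8.84e-11, Fisher's exact test over peaks, against autosomes). A local part in those 5 bins stays open. A larger share of embryos with an inactive X in replicate 1's pool is a candidate explanation that also stays open: 0 of 5 genes known to escape inactivation held a replicate 1 peak where 1.49 were expected from X genes of like length, but the one-sided permutation p of 0.162 is the smallest that 5 genes allow here. The labels give both sexes for each pool without their proportions and the design has 1 group, so no biological explanation was tested between groups.

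Liver transcription factors carried the mark more often than erythroid ones, at 7 of 11 factors of the hepatoblast list against 1 of 9 of the erythroid list (p = 0.0281, Fisher's exact test), with the same counts in each replicate's list. CpG content alone is argued against by the CpG-rich windows, where 7 of 7 and 1 of 4 were marked (p = 0.0242, Fisher's exact test). That comparison rests on only 4 erythroid factors and was chosen after the values were seen. A full share in such windows is not particular to liver factors. It was also found for 47 of 47 neural factors, 23 of 23 heart, muscle and mesenchyme factors, 8 of 8 pancreas and gut factors and 11 of 11 neuronal effector genes. Lower shares were found for 3 of 14 erythroid list genes, 8 of 27 Polycomb genes and 0 of 32 housekeeping genes. Within the hepatic factors the mark did follow CpG content, since all 7 marked ones had CpG-rich windows and none without such a window was marked. A neighbouring peak that only touches the window is argued against by the 7 hepatic factors still marked with 50% of the window covered. That direction is what bulk tissue with hepatoblasts as a minority beside blood cells may give, on the hypothesis that the mark at these factors comes from blood cells (exact p = 0.0281), but the hypothesis was formed on these same values. Mark in hepatoblasts themselves would give the same peaks and stays open, and the coverage of 0 kb at Alb and Afp does not separate the 2 cell types. The design has 1 group, so no biological explanation was tested between groups.

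Of the 6 marked erythroid genes, 5 had an annotated transcript start without a peak, against 2116 of the 4214 other marked genes (50.2%). A marked start that is not the one used by all transcripts, for example an upstream start silent in red cells, may account for these marks, but with 6 genes the shares cannot be told apart (p = 0.218, Fisher's exact test). Hba-x had a peak at both of its 2 annotated starts in the replicated list, with a best −log10 q of 1.29 and no mark in replicate 2's own list, and at Ank1 13 of 16 starts had none. Which starts were in use was not analysed here, and no biological explanation was tested between groups.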
